A study of Homo sapiens with 3 samples.

How the data were processed

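RNA immunoprecipitation followed by sequencing was done in ACHN, an established human renal cell carcinoma line, stably expressing the RNA-binding protein MEX3A with a Flag tag. Per the labels' protocols, cells were fixed with 0.3% formaldehyde, the reaction was stopped with 0.125 M glycine, complexes were captured on protein G beads with an antibody, and the RNA was released with proteinase K. The protocols give DNase I treatment, selection of mRNA on oligo(dT) beads and fragmentation before cDNA synthesis. The labels name 3 samples, which are input RNA, an IgG precipitate and an anti-Flag precipitate, each with 1 library. The IgG and Flag libraries were analysed. The input sample was not analysed here, so RNA levels in the cells were not used and every ratio compares 1 precipitate with the other.

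Both tables list 57820 Ensembl genes with a name and a gene type. The expected counts, estimated counts of reads per gene, were made by the authors in the layout of RSEM gene-level output, per the file headers, and are not normalized. The deposited TPM values are abundances scaled by effective length to a common total, per the file headers. FPKM values were deposited as well and were not used. RSEM, STAR and the builds GRCh37 and hg19 are named in the submitters' processing notes, without versions or roles. The annotation release, the read filters and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart. RSEM-type counting divides reads between genes with shared sequence, so genes with near-identical copies or overlapping neighbours have uncertain counts. Counts were whole, within 0.01, for 86.7% of the detected genes in the Flag library and 89.7% in the IgG library. The gene table provided for reference is of another build, so no coordinates are given, and gene names are those of the files.

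Expected counts were rounded to whole numbers, which summed to 5498124 in the Flag library and 3412864 in the IgG library. CPM values were computed as counts divided by these totals. Genes with at least 20 counts over both libraries entered, and the ratio of Flag CPM to IgG CPM was given an exact 95% Clopper-Pearson interval, computed from the Flag share of the counts of both libraries. A gene was called enriched if the interval lay wholly above 2 and depleted if it lay wholly below 0.5. A count of 0 was replaced by a floor of 3 counts, the limit that a count of 0 allows, and such ratios are given as at least that size. The lower bound of the exact interval, which decided the call, is smaller and stands beside them. The floor equals 0.546 CPM in the Flag library and 0.879 CPM in the IgG library. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per group no difference has a replicate check, no p-value was computed, and a call compares these libraries and not the antibodies in general.

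For 17 gene lists the median log2 ratio of the members was placed among 10000 random lists of the same size matched in 20 bins of mean expression. A list was called lower or higher for a percentile under 2.5 or over 97.5, as a description of these libraries. A scaling adds the same amount to every log2 ratio and shifts every mean expression alike. It therefore cannot move these percentiles beyond ties and rounding, and lists are described relative to matched lists. The 4 scalings moved the percentiles by at most 0.17 and changed 0 list calls, which the method fixes in advance. Of the 14 alternatives run on lists, 4 are these scalings, which do not test a list call. The list symbols not found in the files were RNU2-1, CXCL8, EIF2C1, EIF2C2, EIF2C3, PECAM1 and ZNF120. IL8, AGO1, AGO2 and AGO3, the other symbols of CXCL8 and of the EIF2C genes, were found.

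Lists, thresholds and the rule for named genes were fixed before the data were examined. The rule takes MEX3A to MEX3D, CDX2, CDKN2B and the entering RB/E2F regulators; the 15 enriched genes with the highest lower bound and the 15 depleted genes with the lowest upper bound; up to 2 members at each end of every other list; and the 5 genes with the largest share of each library. It leaves out clone-based names, pseudogenes, XIST and Y-linked genes. A few genes that the rule takes are not reported here. Other members are named where the text says that they were chosen after their values were seen.

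Alternatives set before the data were examined were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), totals without mitochondrially encoded and the 10 most abundant genes, at least 100 counts or no filter, the authors' TPM with a pseudocount of 1 or 0.1, 0.5 counts added, protein-coding genes only, thresholds of 1.5-fold and 4-fold, a 99% interval, lists matched on length too or not matched, and means in place of medians. Genes with whole counts only, and scaling to the 30 nuclear protein-coding genes most abundant in the IgG library, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3, were used.

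The calling was tested on Poisson counts simulated for this comparison over 10791 genes, with unchanged genes at the same mean level in both libraries. It recovered 80% of genes set 4-fold higher, 98% of those set 8-fold higher, 79.6% of those set at 0.25-fold and 100% of those set at 0.125-fold, and called 0 of 10592 unchanged genes. The simulation held counting error only, without variation between libraries or a shift in composition. It gives no rate of false calls for the real libraries. Of 200 random lists of 40 genes, 4% were called without a shift and 98% with a shift of 1 log2 unit.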

Results

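RNA that came down with Flag-tagged MEX3A in ACHN cells was compared with RNA in an IgG precipitate, the background of the method, with 1 library in each group. MEX3A carries KH domains and binds mRNA, and the series concerns its part in the G1/S transition, the RB/E2F pathway and clear cell renal cell carcinoma. The Flag library held 5498124 counts and the IgG library 3412864. At least 10 counts were found for 11667 genes in the Flag library, or 10486 after thinning to the IgG depth, and for 8788 genes in the IgG library. Input RNA was not analysed here.

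A few RNAs filled much of both libraries, in different proportions. MKI67, which encodes the proliferation antigen Ki-67, held 16.6% of IgG counts and 3.92% of Flag counts. CENPF and CENPE, which encode kinetochore proteins, and TPR, which encodes a nuclear pore protein, were also among the 5 largest in the IgG library. In the Flag library the mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 came first, with 20.3% and 9.85% of counts. All mitochondrially encoded RNAs together made up 33% of the Flag library and 8.93% of the IgG library. The 10 most abundant genes held 42.8% of Flag counts and 52.8% of IgG counts.

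The first question was which RNAs were enriched with MEX3A-Flag over IgG. Of 10811 genes that entered, 3100 (28.7%) were enriched and 143 (1.32%) depleted in the Flag library, and 7568 were neither. Counts of enriched and depleted members of lists with total counts, given below, are to be read against these shares. The NF-kappa-B inhibitor NFKBIA was 113-fold higher in the Flag library (95% counting interval 96.0 to 135.1, 25226 against 138 counts). TNFRSF12A, which encodes the TWEAK receptor, was 92.0-fold higher (77.5 to 110.0), and the cytokine gene CSF2 was 37.4-fold higher (26.5 to 54.4). The secreted growth factor binding protein IGFBP7 was 42.2-fold higher (30.9 to 59.2).

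Other genes with the highest lower bounds were RAB43, GRAMD1B, PCGF2, PPP6R1, EML2, DNAJC9-AS1, AP1M2, TCF20, KRCC1 and TIPARP. GRAMD1B, of intracellular cholesterol transport, had 870 Flag counts and 3 IgG counts, a ratio of 180.0 (61.4 to 874.6). The transcription factor gene TCF20 was 34.6-fold higher, TIPARP, which encodes a mono-ADP-ribosyltransferase, 41.3-fold and KRCC1 42.6-fold. AP1M2, which encodes an epithelial clathrin adaptor subunit, had 179 counts against 0 and was at least 37.0-fold higher (lower bound 29.8). PCGF2 (56.6-fold), PPP6R1 (48.9-fold), EML2 (59.8-fold) and DNAJC9-AS1 (207 counts against 0, at least 42.8-fold, lower bound 34.5) had fractional counts, so part of their reads was divided with other genes. The sum of DNAJC9-AS1 and DNAJC9 was 3.63-fold higher (2.77 to 4.84). RAB43, at 2460 counts against 4, overlaps the readthrough gene ISY1-RAB43. The sum of RAB43, ISY1-RAB43 and ISY1 was 26.8-fold higher (21.5 to 33.7).

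Several abundant mRNAs among the depleted genes with the lowest upper bounds had nearly the same factor, a likeness that this ranking favours. Not all abundant mRNAs shared it, since AHNAK had a ratio of 0.571 and FN1 of 0.916. KIF20B, which encodes a mitotic kinesin, was 4.47-fold lower in the Flag library (4.37 to 4.57), the translation initiation factor gene EIF5B 4.41-fold, the early endosome gene EEA1 4.40-fold, the desmoplakin gene DSP 4.43-fold, the golgin gene TRIP11 4.36-fold and the kinectin gene KTN1 4.31-fold. SLTM was 4.78-fold lower, FAM184A 5.97-fold and STXBP2, with 10 counts against 72, 11.6-fold. With the authors' TPM, here and below at a pseudocount of 0.1, FAM184A lost its call (1.89-fold lower) and STXBP2 was 4.09-fold and NBPF24 3.93-fold lower. NBPF24 (13.3-fold), LINC01001 (14-fold) and FP15737 (0 counts against 23, at least 12.3-fold, lower bound 9.26) had fractional counts. The readthrough genes LY75-CD302 and ANKHD1-EIF4EBP3 had 0 Flag counts, against 27 and 21 in the IgG library. Summed with their component genes they gave ratios of 2.73 and 0.950.

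**Figure D1:**
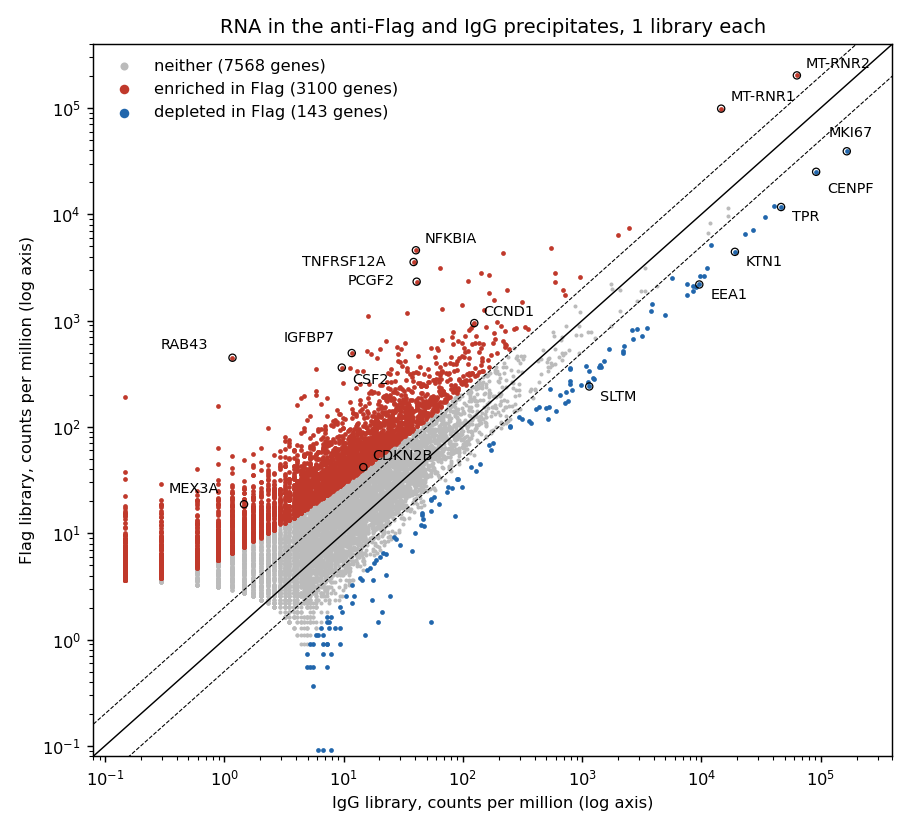
Each point is a gene that entered, with its IgG level on the horizontal axis and its Flag level on the vertical axis, both in CPM on log axes, with 1 library each and genes at 0 drawn near the axis. Enriched and depleted genes are coloured, the solid line marks equal levels and the dashed lines 2-fold differences; NFKBIA lies 113-fold above the line and MKI67 4.23-fold below it on the scale of total counts.

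On the scale of total counts the median log2 ratio was 0.95, with quartiles of 0.10 and 1.88. Where 0 lies depends on which genes fill each library, so this median does not measure enrichment. The 30 nuclear protein-coding genes most abundant in the IgG library held 60.0% of IgG and 16.8% of Flag counts. The 5th and 95th percentiles were -0.93 and 3.31. Across genes, which are not independent replicates, log2 levels correlated with Pearson's r of 0.777 and Spearman's rho of 0.757. TMM scaling lowered every log2 ratio by 0.78 and gave 1293 enriched and 662 depleted genes, so that 66.1% of the called genes were enriched, against 95.6% with total counts. Median-of-ratios scaling gave 1269 and 675 (65.3%), and scaling to the 30 genes most abundant in the IgG library, chosen after seeing the data, gave 8963 and 4.

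MEX3A's own mRNA was 12.8-fold higher in the Flag library (5.31 to 40.2, 103 against 5 counts). Both libraries come from the same overexpressing line, so this value bears on the labels only in part. MEX3C was 6.67-fold higher (4.34 to 10.7) and MEX3D 4.17-fold (2.99 to 5.97), and both were enriched, MEX3D not with TMM scaling. MEX3B had a ratio of 3.72 (1.55 to 10.8) and was not called. CDX2, an intestinal transcription factor gene known as a MEX3A target, had 0 counts in both libraries, which allows up to 0.546 CPM in the Flag and 0.879 CPM in the IgG library.

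The series title raises the question of how RB/E2F regulators of G1/S behave. Of 25 that entered, 11 were enriched and 0 depleted. CCND1, which encodes cyclin D1, was 7.59-fold higher in the Flag library (6.88 to 8.40, 5211 against 426 counts), and its partner kinase gene CDK6 was 5.05-fold higher (4.40 to 5.83). All 3 pocket protein genes were enriched, RBL1 by 15.5-fold (6.97 to 43.0, with fractional counts), RBL2 by 4.68-fold (3.10 to 7.34) and RB1 by 3.77-fold (2.5 to 5.89). CDKN2B, which encodes the CDK4/6 inhibitor p15, was 2.86-fold higher (2.10 to 3.96, 230 against 50 counts). CDK4 did not differ from 1 beyond counting error (0.962, 0.768 to 1.21, with fractional counts).

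The other enriched members were CDKN1A (3.32-fold), CDK2 (3.25-fold, with fractional counts), E2F6 (4.69-fold), E2F7 (3.10-fold) and TFDP2 (3.06-fold). Members that were not called included E2F1 (3.56, 1.86 to 7.48), E2F3 (2.88, 1.98 to 4.31), E2F4 (2.51), TFDP1 (2.28), CDKN1B (2.28), CDKN2C (2.79), CDC25A (1.84), CCND2 (1.19), CCND3 (1.16) and E2F5 (1.18). CCNE1 and E2F8 had the same ratio of 0.621 and E2F2 a ratio of 0.483, with intervals that reached 1 in each case. CDKN2A, with 2 counts in each library, CDKN2D, CDKN1C and CCNE2 did not enter.

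The list's median log2 ratio was 1.51 against 0.87 for matched lists, at percentile 97.88. This call is marginal, since it was lost under 8 of 14 alternatives, with a percentile down to 88.2 for the mean. Of the 14, the 4 scalings could not change it. With TMM scaling 3 members were enriched, and the calls of CDKN2B, CDKN1A, CDK2, RB1, RBL2, E2F6, E2F7 and TFDP2 were lost, likewise with median-of-ratios scaling. CDKN2B, CDK2, E2F7 and TFDP2 also lost their calls with totals without mitochondrial and the 10 most abundant genes, and CDKN2B with TPM. TPM called MEX3B, CDKN1B, E2F1, E2F3, E2F4, TFDP1 and CDKN2C (not at a pseudocount of 1) enriched and CCNE1 depleted, without an interval, and gave ratios of 6.32 for RB1, 0.947 for E2F2 and 0.589 for E2F5.

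**Figure D2:**
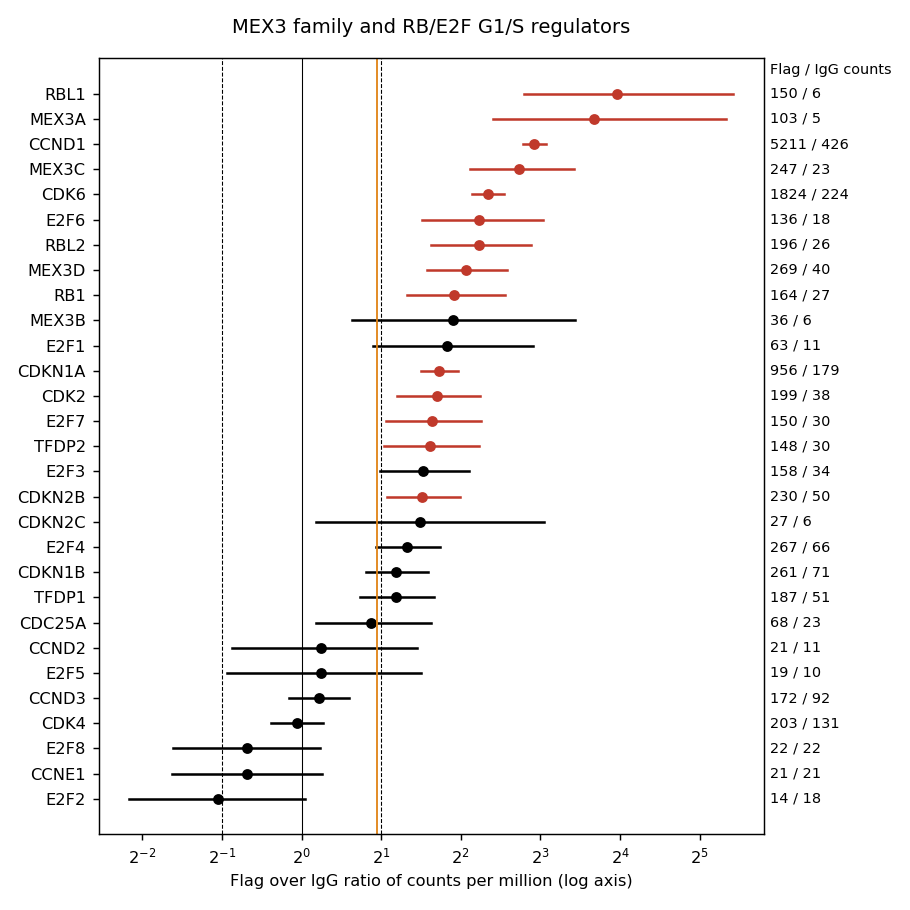
Flag over IgG ratio of CPM on a log axis for the MEX3 family and the RB/E2F regulators that entered, with exact 95% counting intervals as bars and the counts at the right; red marks enriched genes, dashed lines ratios of 0.5 and 2, and the orange line the median gene at 1.93. RBL1, MEX3A and CCND1 lie highest, at 15.5, 12.8 and 7.59, and E2F2 lowest at 0.483.

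Of 39 DNA replication genes that E2F controls, 9 were enriched and 0 depleted (4 and 4 with TMM scaling), and the median log2 ratio of 0.48 lay below that of matched lists at 0.95 (percentile 2.67, not called, but called with 0.5 counts added and with whole counts only). RFC2, a clamp loader gene, was 7.63-fold higher in the Flag library (4.42 to 14.2). MCM5, of the replicative helicase, had a ratio of 0.599 (0.439 to 0.818), and the polymerase gene POLE 0.676 (0.577 to 0.792); both were depleted with TMM scaling, while TPM gave 0.977 for MCM5 and 0.386 for POLE, depleted. Mitosis genes were mixed, with 6 enriched and 2 depleted of 34 (4 and 4 with TMM scaling) and a median of 0.38 (percentile 2.72, not called, but called under 4 of 14 alternatives). KIF11, which encodes a spindle motor, was 15.3-fold higher (11.7 to 20.3) and the checkpoint gene MAD2L1 9.20-fold, though its ratio was 1.34 with TPM and the call was lost. CENPF was 3.65-fold and CENPE 3.40-fold lower.

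The list of immediate-early and AU-rich unstable mRNAs was called higher than its matched lists. Half-lives and AU-rich elements were not measured here. Of 43 immediate-early and AU-rich unstable mRNAs, 21 were enriched (13 with TMM scaling) and 0 depleted. The median of 1.61 lay above that of matched lists at 0.86 (percentile 99.88). The call was kept under all 14 alternatives, of which the 4 scalings could not change it. NFKBIA and CSF2 had the highest lower bounds. Further members, named after their values were seen, were the chemokine genes IL8 (14.5-fold, 11.8 to 17.9), CXCL2 (9.96-fold) and CXCL1 (6.86-fold), the cytokine gene LIF (9.34-fold), the matricellular gene CYR61 (16-fold, 14.7 to 17.5) and the antiproliferative gene BTG2 (10.4-fold). MYC (0.820, 0.675 to 0.997) and IER2 (0.765, 0.550 to 1.07) had the lowest upper bounds and were not called. In all 22 members were not called, among them DUSP1 (0.888), IL6 (1.69) and EGR1 (3.06).

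mRNAs of P-body and RNA decay factors, proteins of the granules in which MEX3 proteins reside, were higher than their matched lists too. Of 44, 22 were enriched and 0 depleted (7 and 2 with TMM scaling), and the median of 1.49 lay above 0.95 in matched lists (percentile 98.56, lost with TPM at both pseudocounts and with the mean). DCP1A, a decapping gene, was 18.8-fold higher (10.6 to 36.8, and 9.47-fold with TPM) and LSM3 11.3-fold (6.17 to 23.0). AGO2 (6.56-fold), the 5'-3' exonuclease gene XRN1 (5.05-fold) and PUM2 (4.61-fold), named after their values were seen, were also enriched. PAN2 had a ratio of 0.272 (0.134 to 0.524) and EDC4, with fractional counts, 0.591 (0.444 to 0.786), and neither was called, though both were depleted with TMM scaling and PAN2 with TPM (0.135). Of 39 zinc finger genes of the ZNF series, 18 were enriched (10 with TMM scaling) and 0 depleted, with a median of 2.19 against 1.22 in matched lists (percentile 99.93, lost at a minimum of 100 counts). ZNF37A was 24.2-fold higher (9.27 to 90.0) and ZNF92 13.2-fold, while ZNF205 (0.784) and ZNF221 (0.859) were not called. TPM gave ZNF221 a ratio of 0.449, depleted, or 0.554 at a pseudocount of 1, not called.

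Several lists lay below their matched lists. For 43 replication-dependent histone mRNAs, which lack poly(A) tails, the median was -0.76 against 0.90 (percentile 0), with 0 enriched and 4 depleted, 18 with TMM scaling. HIST1H2BJ was 10.9-fold (18.9-fold with TPM) and HIST1H2BO 6.67-fold lower, and HIST1H2AL (1.16) and HIST1H4H (0.916) lay below the median gene at 1.93. For 76 cytosolic ribosomal protein mRNAs the median was -0.21 against 0.90 (percentile 0). Of these, 4 were enriched, among them RPL24 (5.89-fold) and RPL5 (4.41-fold), and 1 with fractional counts was depleted. With TMM scaling 26 were depleted. RPS12 had a ratio of 0.367 (0.258 to 0.518) and was among those 26, and was depleted with TPM too.

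For the 22 members of the list of nuclear noncoding RNAs the median was -0.26 against 0.85 (percentile 0.05), with SCARNA2 2.68-fold and KCNQ1OT1 2.24-fold lower (KCNQ1OT1 not called with TPM at a pseudocount of 1) and 11 depleted with TMM scaling. This list also holds RN7SL1, RN7SL2, GAS5 and SNHG genes, whose RNAs are not confined to the nucleus. Its median therefore does not describe nuclear RNA alone. JPX, with 52 counts against 1, was the only member enriched, at a ratio of 32.3 (5.54 to 1299), and MEG3, with fractional counts, had a ratio of 1.57. Nuclear-encoded oxidative phosphorylation genes had 9 enriched and 2 depleted of 50 (3 and 10 with TMM scaling) and a median of 0.42 against 0.91 (percentile 1.48), a call that was lost when length was matched and at a minimum of 100 counts (percentile 69.5). NDUFB5, with 48 counts against 0, was at least 9.93-fold higher (lower bound 7.77) and NDUFB8, with fractional counts, 7.76-fold, while COX5A was 7.36-fold and CYC1 3.33-fold lower. The 13 renal epithelial markers had 4 enriched and 0 depleted (1 and 2 with TMM scaling) and a median of -0.07 against 0.83 (percentile 1.56), lost under 5 of 14 alternatives, with whole counts only among them (percentile 53.0). PAX2, a kidney transcription factor gene, was 5.20-fold and LHX1 5.51-fold higher, while KRT18 (0.673, with fractional counts) and HAVCR1 (0.681) were not called. With TMM scaling LHX1 lost its call, and KRT18 and HAVCR1 were depleted.

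**Figure D3:**
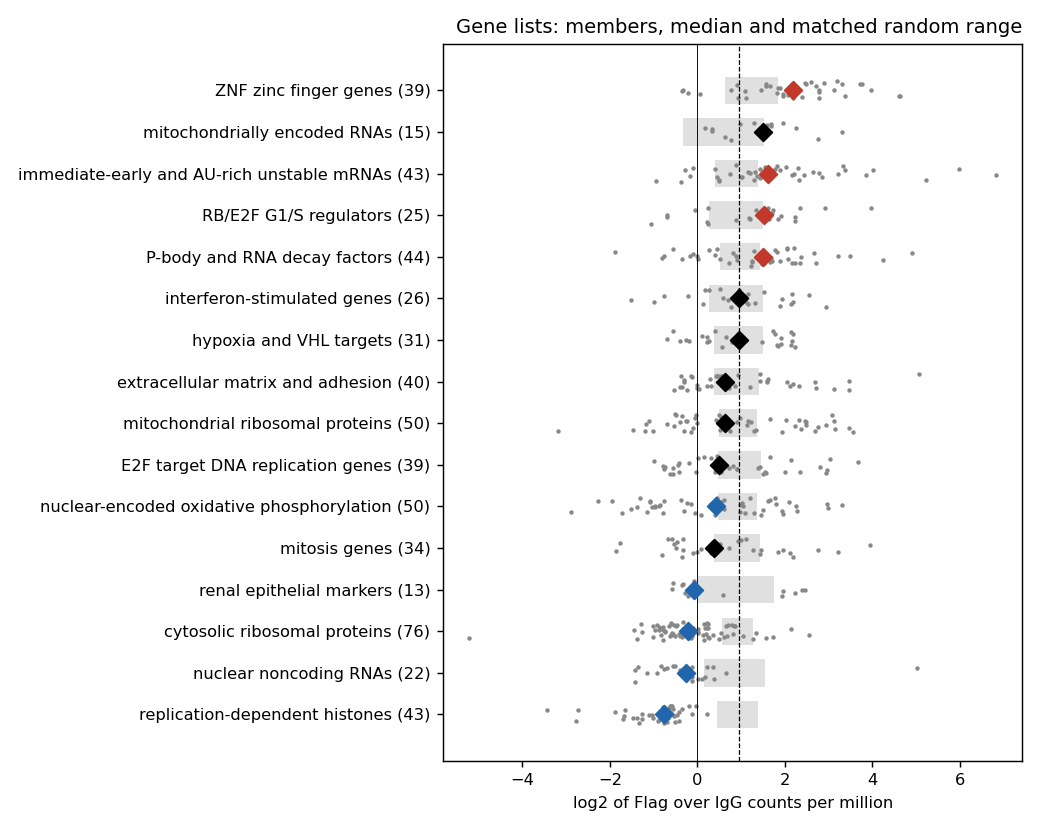
Log2 of Flag over IgG CPM for the members of each list with at least 5 entering genes (grey points), the list median (diamonds, red if higher and blue if lower than matched lists, black if not called) and the central 95% of medians of matched random lists (grey bands). The dashed line marks the median gene at 0.95, and the histone list lies lowest, at -0.76; a scaling moves points, medians and bands together.

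Mitochondrially encoded RNAs had unequal ratios. Of 15, 9 were enriched and 0 depleted (4 and 0 with TMM scaling), and the median of 1.5 stood against 0.64 in matched lists (percentile 97.2, not called, but called under 4 of 14 alternatives). MT-ATP8 was 9.90-fold higher (8.02 to 12.3), MT-RNR1 6.72-fold (6.66 to 6.79) and MT-RNR2 3.20-fold (3.19 to 3.22). MT-ATP6, which overlaps MT-ATP8, was 2.83-fold higher (2.70 to 2.96), so the ratio of MT-ATP8 may depend on how reads were assigned between them. MT-CO1 (1.26, 1.22 to 1.30, with fractional counts) and MT-CO2 (1.12, 1.06 to 1.19) lay below the median gene. With TMM scaling the call of MT-RNR2 was lost and the ratios of MT-CO1 and MT-CO2 were below 1.

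**Figure D4:**
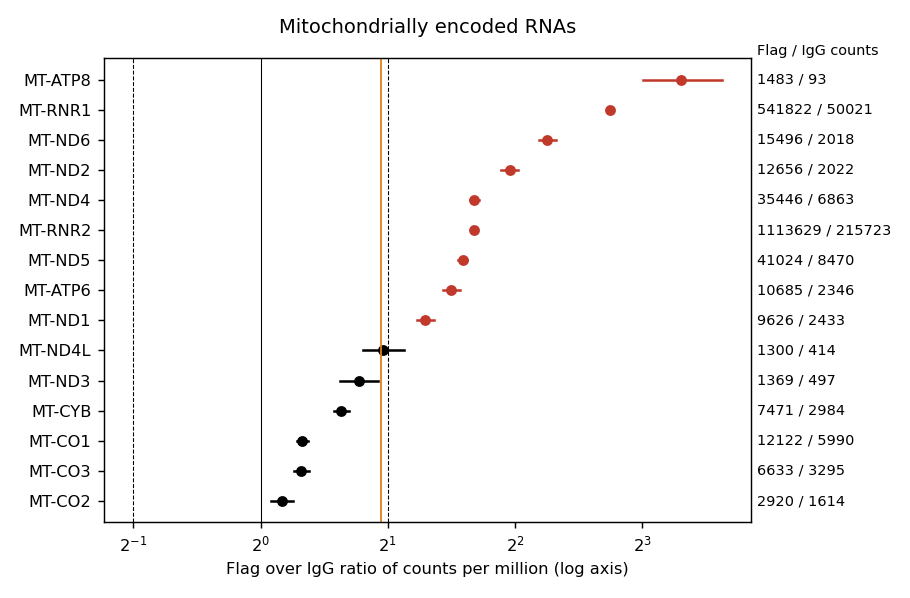
Flag over IgG ratio of CPM on a log axis for the 15 mitochondrially encoded RNAs, with exact 95% counting intervals as bars and the counts at the right; red marks enriched RNAs, dashed lines ratios of 0.5 and 2 and the orange line the median gene at 1.93. Ratios run from 1.12 for MT-CO2 to 9.90 for MT-ATP8.

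The remaining lists were not called. Of 50 mitochondrial ribosomal protein genes, 15 were enriched and 1 depleted (9 and 5 with TMM scaling, median 0.64, percentile 11.5). MRPS22 was 11-fold and MRPL18 8.86-fold higher, MRPS18A, with 3 counts against 17, had a ratio of 0.110 (0.0206 to 0.379), and MRPS23 had a ratio of 0.359 and was not called, but was depleted with TMM scaling and with TPM. Of 40 extracellular matrix and adhesion genes, 16 were enriched and 0 depleted (8 and 0 with TMM, 7 and 2 with median-of-ratios scaling, median 0.64, percentile 16.8), led by the integrin genes ITGA1, with 161 counts against 3 (33.3, 11.2 to 163.2, with fractional counts), and ITGB8, with 53 against 0 (at least 10.9-fold, lower bound 8.61). LAMA5 (0.759) and HSPG2 (0.810, with fractional counts) had the lowest upper bounds and were the 2 depleted with median-of-ratios scaling, and LAMA5 was depleted with TPM too (0.370).

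Hypoxia and VHL targets, a pathway altered in clear cell renal cell carcinoma, had 9 enriched and 0 depleted of 31 (1 and 2 with TMM scaling, median 0.95, percentile 54.3). INSIG2, with 22 counts against 0, was at least 4.55-fold higher in the Flag library (lower bound 3.40, not called with TMM scaling), while ENO1 (0.682) and ALDOA (0.755) were not called, and were depleted with TMM scaling. Interferon-stimulated genes had 7 enriched and 0 depleted of 26 (3 and 1 with TMM scaling, median 0.95, percentile 63.1). SAMHD1, with fractional counts, was 5.83-fold and OAS3 4.38-fold higher, and DHX58 (0.349, depleted with TMM scaling and with TPM, though not at a pseudocount of 1) and MX1 (0.502, and 0.803 with TPM) were not called. Among 30 markers of blood, immune, endothelial and fibroblast cells, 2 entered (percentile 53.9), ACTA2 with a ratio of 2.79 (1.39 to 6.22) and CD68 with 1.43 (0.725 to 2.99), both with fractional counts, and neither was called, though TPM gave 3.54 and 2.89, both enriched.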

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

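No paired analysis was possible because each group has 1 library. Medians below are log2 values, and those of lists are relative to matched lists. The tests with whole counts only and with scaling to the 30 genes most abundant in the IgG library were chosen after seeing the data. The calls of the immediate-early, histone, cytosolic ribosomal protein and nuclear noncoding lists kept their side of the threshold under every alternative that gave a value. The 4 scalings among these moved no list percentile by more than 0.17 and by their method could not change a list call. At this depth 80% of 4-fold enrichments simulated with counting error only were recovered, and smaller ones were not simulated. Except where the scaling, threshold or filter sets the difference by construction, the cause was not tested.

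Enriched and depleted genes numbered 1293 and 662 with TMM, 1269 and 675 with median-of-ratios scaling, 5170 and 1150 with TPM and a pseudocount of 1, 6029 and 1497 with a pseudocount of 0.1, 8963 and 4 with scaling to the 30 genes, and 924 and 24 beyond 4-fold. Depleted genes numbered 228 with totals without mitochondrial and the 10 most abundant genes, 218 without the filter and 298 beyond 1.5-fold. The median log2 ratio, 0.95 with total counts, was 0.17 with TMM, 0.16 with median-of-ratios scaling, 0.71 with the reduced totals, 1.04 at 100 counts, 0.53 without the filter, 0.65 and 0.81 with TPM at pseudocounts of 1 and 0.1, and 2.81 with scaling to the 30 genes. On the scale of total counts, a log2 ratio of 0 under these scalings lies at 0.78 for TMM, 0.79 for median of ratios, 0.24 for reduced totals and -1.87 for the 30 genes.

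Scaling to the 30 genes also turned 26 named genes from below to above 0, of which 11 were called neither with total counts nor with this scaling; the other 15 were CDK4 (1.81), POLE (1.30), CENPE (0.10), CYC1 (0.13), HIST1H4H (1.74), SCARNA2 (0.45), KCNQ1OT1 (0.70), LAMA5 (1.47), HSPG2 (1.56), MYC (1.58), IER2 (1.48), ENO1 (1.31), ALDOA (1.46), KRT18 (1.29) and HAVCR1 (1.31).

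The RB/E2F list was no longer called at 100 counts (0.63), with TPM (0.52 and 0.60), with protein-coding genes only (0.62), with whole counts only (0.57), with length matched (0.57), without matching (0.57) and with the mean (0.31). Mitosis genes became called at 100 counts (-0.58), with protein-coding genes only (-0.52), with whole counts only (-0.51) and without matching (-0.56), and E2F target replication genes with 0.5 counts added (-0.49) and with whole counts only (-0.50). Mitochondrially encoded RNAs became called at 100 counts (1.10), with TPM (1.10 and 1.11) and with length matched (0.92). The P-body list was lost with TPM (0.36 and 0.38) and with the mean (0.31), and the ZNF list at 100 counts (0.70). The oxidative phosphorylation list was no longer called at 100 counts (0.16, of opposite sign) and with length matched (-0.12). Renal markers were no longer called with whole counts only (0.038, of opposite sign), without the filter (-0.029), with TPM (-0.55 and -0.65) and with the mean (-0.18). Among lists not called, mitochondrial ribosomal proteins moved to 0.34 at 100 counts and 0.066 with length matched, extracellular matrix to 0.017 with TPM at a pseudocount of 1 and 0.10 with the mean, hypoxia targets to -0.014 with protein-coding genes only, -0.038 with whole counts only and -0.034 with the mean, interferon-stimulated genes to -0.29 and -0.38 with TPM, -8.3e-05 with length matched and -0.0012 with the mean, and markers of other cell types to -0.10 without the filter.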

Other observations

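The tests in this part were chosen after the results were seen, except for the matching of lists on length, which was planned. Genes were also grouped by the letters that open their symbols, and 80 such families had at least 12 members, of which about 2 would pass the thresholds each way by chance. The 4 families higher than matched lists were ZNF genes (240 genes, 78 enriched, percentile 99.96), TMEM genes of transmembrane proteins (122, 38 enriched, 99.57), ARL genes, many of them of small GTPases of membrane traffic (20, 9 enriched, 99.48), and PIK genes of phosphoinositide kinases (12, 8 enriched, 98.97). Of all genes that entered, 28.7% were enriched. The ZNF family takes in genes of the ZNF list called above, so it is not a separate observation. The members with the highest lower bounds were ZNF726 (17.8-fold) among ZNF genes, TMEM86B (19.9-fold) among TMEM genes and PIK3R1 (9.24-fold) among PIK genes. Besides histones and ribosomal proteins, lower groups were NBPF (12 genes, percentile 0.02), ATP (57, 0.38), autophagy ATG (14, 1.04), syntaxin-type STX (15, 1.35), kinesin KIF (27, 1.73) and NDUFA (12, 2.27) genes. Families were matched on mean expression and not on length. The oxidative phosphorylation list, which holds NDUFA genes, lost its call with length matched (percentile 28.4). NBPF genes are near-identical copies, so their counts are uncertain.

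Among gene types, 10 snoRNAs had a median log2 ratio of -1.40 with 5 depleted and 0 enriched (percentile 0). Processed transcripts (68, percentile 0.01) and pseudogenes (206, percentile 0.32) lay lower than matched genes, while lincRNAs (152, percentile 64.6) and antisense genes (150, percentile 40.6) did not stand apart. Collagen mRNAs of the matrix list differed: COL4A1 was 8.77-fold higher (8.36 to 9.19) while COL4A2 had a ratio of 1.02 (0.972 to 1.08), both chosen after their values were seen.

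The 30 nuclear protein-coding genes most abundant in the IgG library, led by MKI67 and CENPF, held 60.0% of its counts and 16.8% of Flag counts, and 25 of them were depleted, with a median log2 ratio of -1.87 and quartiles of -2.07 and -1.49. Their log2 ratios ran from -2.16 to -0.126. A candidate explanation is background retained alike in both precipitates and diluted in the Flag library, which would set a floor on the ratio. Outside the 30, 64 depleted genes had whole counts, enough to show a ratio of 0.5 times the lowest of the 30, and 4 of them (6.25%: STXBP2, MYH16, FAM184A and SLTM) lay wholly below that lowest ratio, between the limits of 5% and 20% set for and against a floor; with the authors' TPM 1 of these 4, MYH16 (0.0946), lay below the lowest TPM ratio of the 30 (0.218), FAM184A lay at 0.528, and this stays open. Lower recovery of long transcripts is argued against by 741 other long protein-coding genes, whose median was 1.30. Binding of A-rich RNA to the oligo(dT) or protein G beads was not tested, since no sequence was used here, and with 1 library each a difference between libraries unrelated to MEX3A stays open too.

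The height of the immediate-early and AU-rich list, with NFKBIA, CSF2, CYR61 and IL8, may reflect association of these mRNAs with MEX3A-Flag. Transcript length is argued against by a percentile of 99.84 with length matched, and division of reads between genes by 99.65 among genes with whole counts. More nuclear RNA in the Flag precipitate is argued against by MALAT1 (1.12), NEAT1 (1.16) and KCNQ1OT1 (0.447), all below the median gene at 1.93. Open remain a difference in how the cells of the precipitates were handled, which these short-lived mRNAs could follow, and amplification of single fragments, which needs read positions.

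Mitochondrially encoded RNAs, a list that was not called (percentile 97.2), ranged from MT-CO2 at 1.12, below the median gene at 1.93, to MT-ATP8 at 9.90. MT-ATP6, which overlaps MT-ATP8, lay at 2.83, so this top value is uncertain. The next highest was MT-RNR1 at 6.72. More mitochondria of the same RNA make-up would give 1 ratio if both libraries were selected and counted alike. The lower bound of MT-RNR1 lay 5.14-fold above the upper bound of MT-CO1. Under that condition such mitochondria alone would not give these ratios. Poly(A) selection may have differed between the libraries, so the gap cannot exclude more mitochondria. Weaker poly(A) selection of the Flag library would raise histone mRNAs, which lack poly(A) tails. The histone list lay at percentile 0 among matched lists, which the precipitation itself may raise. Its median log2 ratio of -0.76 lay above that of the 30 genes most abundant in the IgG library (-1.87). The answer thus depends on the genes compared, and this stays open. Mitochondria retained with a different RNA make-up, or binding after lysis, stay open as untested.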
